A study of Mus musculus with 6 samples.

How the data were processed

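RNA from lung ILC2s of WT (R5/+) and KO (R5/+ with floxed Rptor) mice was converted to full-length cDNA with a SMART-Seq kit and made into libraries with a TruePrep kit, per the labels' protocols. The cDNA kit does not mark the strand of the RNA. HISAT2, Cufflinks and the genome build mm10 are named in the submitters' processing notes, without versions or roles; the counting tool, its strand setting and the annotation are not given in the sources used here. Reads of antisense or overlapping genes, and of near-identical gene copies, may therefore be split between genes. Groups came from the sample titles. The deposited count table holds raw counts per gene for 37749 Ensembl gene IDs, with whole numbers and column totals from 11220835 to 12166192 that differ between libraries. Names and coordinates came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes, for 37494 IDs; 255 IDs stayed without a name.

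A second table that the authors named FPKM was deposited beside the counts. In it, between 26.2% and 32.1% of the genes with a count in a library have negative values, which correspond to a gene length below 0, and the depth divisor cycles through 6 values down the rows instead of being fixed per library; other genes have an implied length that differs between libraries. Its values were used only in alternatives, on genes without a negative value in any library, with a pseudocount of 1 or 0.1, a mean of at least 1 or no filter, and limma-trend; fold changes are then on the log2(value + pseudocount) scale.

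The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts of the 6 libraries, KO against WT, with genes kept by filterByExpr (minimum count 10, minimum total 15), TMM normalization, no replicate block, and Benjamini-Hochberg adjustment over 14530 tested genes with a threshold of 0.05. The adjusted p of a gene is always from this test unless another is named. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM with TMM effective library sizes, given as mean ± SD of 3 libraries. The biological coefficient of variation was 0.253, and Spearman correlations between libraries lay between 0.841 and 0.863. Exact two-sided permutation tests were run on Rptor and Nmur1 alone.

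Before the data were examined, 33 gene lists of pathways and of other cell types were fixed and tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; an estimated correlation and fry were alternatives. The rule for named genes was also fixed then. It takes 10 genes of prior interest, the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, leaving out numbered gene models, pseudogenes and antigen receptor segments, and for each list up to 4 members with the smallest p past the threshold, or the 2 with the smallest p as values where fewer than 2 passed. For lists with little change the counts alone are given in places. The rule takes 107 genes, of which 74 passed the threshold; Rps3a2 and the other pseudogenes in the closing section, the genes of IL-17-producing cells and the TFEB and TFE3 targets lie outside it. Some genes that the rule or a list takes are not reported here.

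The steps were tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes. Of genes changed 1.5-fold, 1.49% were recovered in the simulated KO against WT comparison of 13905 genes, 37.3% of those changed 2-fold and 71.2% of those changed 4-fold, and 2 of 75 calls were unchanged genes. In this simulation 1.5-fold changes were thus nearly all missed and 2-fold changes often. It held fewer changed genes than the 581 called in the real data, so these shares may not carry over. In a second simulation camera called the shifted list and 0 of 33 unshifted lists. The simulated genes were drawn independently, so false calls in lists of correlated genes were not tested. In the real data the estimated correlation of the ribosomal protein list was 0.576.

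Alternatives fixed before the data were examined were 2 other normalizations, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter and a filter of 10 CPM in 3 libraries, the replicate number as a block, a fold change threshold, the FPKM values and each library left out in turn. After the data had been seen, 2 more were added: leaving out WT 1 and KO 3, the libraries with the most genes detected, and adding the mean log2 CPM of 15 macrophage markers as a covariate.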

Results

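Bulk RNA-seq was deposited for group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes without antigen receptors that secrete type 2 cytokines, sorted from mouse lung. The 6 libraries fall into 2 groups of 3. WT cells carried one R5 allele, a reporter inserted at Il5 that also drives Cre recombinase, and KO cells carried R5 together with 2 loxP-flanked copies of Rptor, which encodes Raptor, the subunit that defines the kinase complex mTORC1. The labels give conflicting accounts of the animals' state: the series text places the cells after papain, a protease allergen, and the sample protocol describes the steady state, so which applies to these libraries is open. Total counts per library ranged from 11220835 to 12166192, and between 24493 and 30824 genes had at least 1 count. WT 1 and KO 3 had the most genes detected, 30824 and 29176. Counts of Xist were between 0 and 4 per library and those of Ddx3y between 2861 and 4235, so every library carried male transcripts. Nothing in the labels says that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical.

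The comparison of KO with WT addresses how mTORC1 in ILC2s shapes their expression programme, including Nmur1, the receptor for the neuropeptide neuromedin U that the series title names. Rptor (ENSMUSG00000025583, GRCm38 chromosome 11, 119602905 to 119899576, plus strand) was measured at 50.9 ± 6.75 CPM (counts scaled to library size; SD, n = 3) in WT and 34.6 ± 6.43 (SD, n = 3) in KO. The WT libraries held 45.6, 48.6 and 58.5 CPM and the KO libraries 28.6, 33.7 and 41.4, so each KO library lay below each WT library. The log2 fold change was −0.56 ± 0.17 (SE) with an edgeR adjusted p of 0.0933, which does not pass the threshold of 0.05. The exact two-sided permutation test of the 6 log2 CPM values gave p = 0.1, the smallest that 3 against 3 allows. The counts cover the whole gene, so transcripts that lack the deleted exons still count, and Rptor is only a partial check of the labels. Cells in which Cre had not deleted Rptor would also add counts, and their share was not measured. Without KO 3 the edgeR adjusted p was 0.0426 at a log2 fold change of −0.71, and over all alternatives it ranged from 0.0402 (DESeq2) to 0.583.

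Nmur1 (ENSMUSG00000026237, chromosome 1, 86386303 to 86426228, minus strand) fell from 200.2 ± 45.4 CPM in WT to 97.6 ± 33.01 in KO (SD, n = 3 each), a log2 fold change of −1.04 ± 0.22 (SE; edgeR adjusted p = 0.0242). All 3 KO libraries lay below all 3 WT libraries, and the exact two-sided permutation p was again 0.1. The call depended on single libraries: the adjusted p was 0.0758 without WT 2, 0.147 without WT 3, 0.0561 without KO 2 and 0.0602 without KO 3, with log2 fold changes between −1.36 and −0.84 over the 6 such fits. It was also lost on the deposited FPKM values, at adjusted p between 0.0545 and 0.154, and over all alternatives the adjusted p ranged from 8.07e-09 (no filter) to 0.684 (macrophage marker covariate). Within the 18 tested receptors for neuropeptides, neurotransmitters and related mediators, 3 fell and none rose. The other members that fell were Ramp1, the partner subunit of the receptor for calcitonin gene-related peptide, from 368 ± 40.8 to 166 ± 39.3 CPM (log2 fold change −1.15, adjusted p = 0.00406), and Cysltr1, a receptor for cysteinyl leukotrienes, from 109 ± 11.1 to 57.2 ± 5.57 CPM (−0.93, adjusted p = 0.00335). Adjusted over the list alone, 5 fell. As a list these receptors did not pass camera (adjusted p = 0.0706, median log2 fold change −0.07; 0.588 with an estimated correlation), though they did without WT 1 (adjusted p = 0.0219) and without KO 1 (0.0332). Ramp1 and Cysltr1 stayed past the threshold in each of the 6 fits that left out 1 library.

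Across the transcriptome, 14530 genes were tested with edgeR. Of these, 302 were higher and 279 lower in KO at an adjusted p under 0.05, which is 4% of those tested. At an unadjusted p under 0.05 there were 2868. Fold changes above 2 were found for 176 of the higher and 103 of the lower genes. For 295 of the higher and 279 of the lower genes the KO and WT libraries did not overlap, but called genes were selected for separation. Over all tested genes 25.2% had no overlap, an arrangement that chance gives for 10% of genes in 3 against 3. The counts varied with the libraries used: 135 higher and 141 lower without WT 1, 101 and 61 without WT 2, 88 and 56 without WT 3, 130 and 123 without KO 1, 300 and 337 without KO 2, and 374 and 352 without KO 3.

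**Figure D1:**
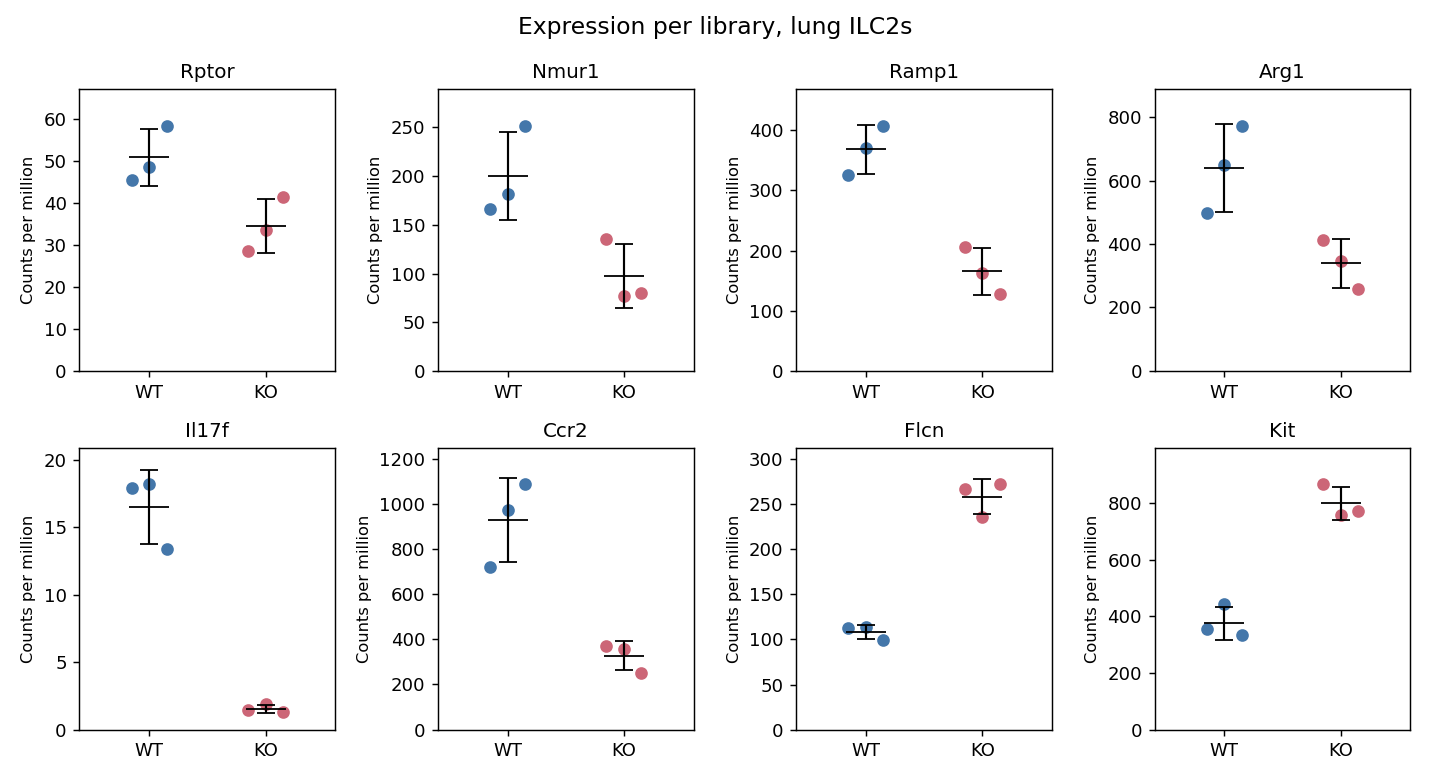
CPM of 8 genes in the 3 WT and 3 KO libraries, each panel with CPM on a linear vertical axis from 0; points are libraries, horizontal bars means and whiskers the SD. Rptor, Nmur1, Ramp1, Arg1, Il17f and Ccr2 lie lower in all 3 KO libraries, and Flcn and Kit lie higher; Rptor does not pass the threshold of the edgeR test (adjusted p = 0.0933).

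Among ILC2 transcription factors, surface markers and enzymes, 1 of 26 tested members rose and 3 fell, with the remaining 22 not past the threshold. Adjusted over the list alone, 2 rose and 6 fell. Hpgds, the hematopoietic prostaglandin D synthase, rose from 16.9 ± 2.76 to 69.1 ± 5.01 CPM (log2 fold change 2.03, adjusted p = 9.45e-05). Cxcr6, a chemokine receptor, fell from 2611 ± 262 to 1152 ± 344 CPM (−1.18, adjusted p = 0.00807). Arg1, encoding arginase 1, fell from 640.4 ± 138 to 339 ± 77.4 CPM (−0.92, adjusted p = 0.0238), and the transcriptional cofactor Lmo4 fell by 0.53 on the log2 scale (adjusted p = 0.0363). The type 2 lineage factor Gata3 was at 2432 ± 265 CPM in WT and 3292 ± 198 in KO (log2 fold change 0.44, adjusted p = 0.0648). Il1rl1, the IL-33 receptor, was at 859 ± 114 and 841 ± 118 (−0.03, adjusted p = 0.943). Klrg1 was at 385 ± 48.3 and 329 ± 36.2 (−0.23, adjusted p = 0.417). The list as a whole did not pass camera (adjusted p = 0.203). It passed in the lower direction without KO 2 (0.0106), and in the higher direction with the macrophage marker covariate (0.0156). Cxcr6 missed the threshold without WT 3 (adjusted p = 0.0569), Arg1 without WT 2 or WT 3 (0.105 and 0.147), and Lmo4 in 5 of the 6 fits that left out 1 library, all but that without KO 3 (0.0567 to 0.216), while Hpgds kept it in all 6.

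Of 28 tested effector cytokines and secreted mediators, 2 rose and 6 fell (2 and 8 adjusted over the list alone). Il5 was at 334 ± 14.997 CPM in WT and 233 ± 107 in KO, a log2 fold change of −0.52 with an adjusted p of 0.323. Il13 was at 20.1 ± 5.34 and 20.5 ± 10.2 CPM (0.02, adjusted p = 0.977). Areg, encoding the tissue repair factor amphiregulin, was at 1212 ± 139 and 899 ± 123 (−0.43, adjusted p = 0.111). Il17a fell from 12.9 ± 4.26 to 1.84 ± 0.77 CPM (−2.80, adjusted p = 0.00259) and Il2 from 50.5 ± 7.55 to 27.6 ± 3.47 CPM (−0.87, adjusted p = 0.015). Ccl3 and Ccl4, chemokines that attract leukocytes, rose by log2 fold changes of 1.67 and 1.46 (adjusted p = 0.0161 and 0.0181). The list passed camera in the lower direction (adjusted p = 0.0455, median −0.13) but not with an estimated correlation (adjusted p = 0.678), and not without WT 1, WT 2, KO 1 or KO 3 (adjusted p between 0.0504 and 0.208). It also missed the threshold with a filter of 10 CPM in 3 libraries (0.237) and on the FPKM values (0.111). Ccl3 and Ccl4 lost the threshold without any one WT library (adjusted p between 0.0619 and 0.101), and Il2 without WT 2, WT 3 or KO 1 (0.0672 to 0.114).

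Of 30 alarmin, cytokine and costimulatory receptors, 2 fell (1 higher and 4 lower adjusted over the list alone): Icos, a costimulatory receptor, from 1094 ± 59.3 to 666 ± 159 CPM (−0.72, adjusted p = 0.0309), and Tnfrsf25, the receptor for TL1A, from 235 ± 14.6 to 164 ± 7.04 CPM (−0.51, adjusted p = 0.0285). The list passed camera in the lower direction (adjusted p = 0.0147; 0.678 with an estimated correlation) but not without WT 2 (0.203) or KO 3 (0.13), nor with a filter of 10 CPM in 3 libraries (0.0533). Both genes missed the threshold without WT 1, WT 2, WT 3 or KO 1 (adjusted p between 0.0733 and 0.185). Of 19 tested inhibitory receptors and signalling inhibitors, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.446). Cd96, an inhibitory receptor, fell from 198 ± 14.8 to 103 ± 6.08 CPM (−0.94, adjusted p = 0.0016), and Socs3, an inhibitor of cytokine signalling, rose from 35.9 ± 10.5 to 98.5 ± 8.04 CPM (1.45, adjusted p = 0.00167). Havcr2 and Lair1 rose by log2 fold changes of 1.26 and 2.31 (adjusted p = 0.0167 and 0.0349); both lost the threshold without WT 1, WT 3 or KO 1 (0.0608 to 0.154), and Lair1 also without KO 3 (0.083). Both were higher in KO, as were the macrophage markers given below.

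Genes of migration and tissue retention were lower as a list: 7 of 24 tested members fell and 1 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00117, median −0.33; 0.588 with an estimated correlation). Ccr2, a chemokine receptor, fell from 927 ± 186 to 327 ± 64.4 CPM (−1.50, adjusted p = 0.0015). Gpr183, an oxysterol receptor that guides lymphocyte positioning, fell from 280.3 ± 16.2 to 158 ± 10.8 CPM (−0.82, adjusted p = 0.00329). Ccr6 fell from 14.1 ± 2.49 to 3.46 ± 1.39 CPM (−2.02, adjusted p = 0.00568). These 3 genes kept the threshold in all 6 fits that left out 1 library. Of 12 tested ILC3 markers, 1 rose and 3 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.149). The list passed in the lower direction with a filter of 10 CPM in 3 libraries (adjusted p = 0.0388, 7 members) and on the FPKM values (0.0103, 9 members). Il17f fell from 16.5 ± 2.71 to 1.55 ± 0.30 CPM (−3.40, adjusted p = 0.000173), and Kit, the stem cell factor receptor, rose from 377 ± 58.2 to 799 ± 58.8 CPM (1.08, adjusted p = 0.00167).

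Lysosomal and autophagy genes, which include targets of the transcription factors TFEB and TFE3, were higher in KO. Of 55 tested members 14 rose and 1 fell (22 and 1 adjusted over the list alone), and 47 had a positive fold change, with a median log2 fold change of 0.37 (camera adjusted p = 1.25e-11). This was the only list past the threshold with an estimated correlation (adjusted p = 0.0291), and it passed fry (adjusted p = 0.0029). Flcn, encoding folliculin, a regulator of mTORC1 at the lysosome, rose from 108 ± 7.94 to 258 ± 19.5 CPM (1.25, adjusted p = 0.000336). The protease Ctsl rose from 26.8 ± 4.75 to 60.8 ± 2.93 CPM (1.18, adjusted p = 0.00215). The tetraspanin Cd63 rose from 27.9 ± 9.86 to 73.8 ± 5.16 CPM (1.40, adjusted p = 0.0063). Gaa, the lysosomal alpha-glucosidase, rose from 58.5 ± 6.93 to 119.6 ± 24.5 CPM (1.03, adjusted p = 0.00609). Gaa missed the threshold without WT 3 (adjusted p = 0.0516), and the others kept it in all 6 fits. Among 35 tested mTOR components and regulators, 1 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.333): Rragd, encoding the RagD GTPase, went from 1.45 ± 0.44 to 5.03 ± 0.62 CPM (1.79, adjusted p = 0.0352), a call lost in each fit that left out 1 library (adjusted p between 0.05 and 0.162).

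Macrophage markers moved in the same direction as the lysosomal genes. Of 25 tested macrophage, monocyte and dendritic cell markers 13 rose and 1 fell (17 and 2 adjusted over the list alone), with a median log2 fold change of 1.69 (camera adjusted p = 1.28e-09; 0.304 with an estimated correlation). C1qb, a complement component, rose from 3.15 ± 1.21 to 18.98 ± 3.17 CPM (2.59, adjusted p = 0.00148). Chil3, a chitinase-like protein abundant in alveolar macrophages, rose from 104 ± 17.1 to 378 ± 152 CPM (1.86, adjusted p = 0.00267). The member that fell was Ccr2, described above. Summed over 15 macrophage markers, picked from this list after the data were examined and none of them in the lysosomal list, the libraries held 345 ± 97.3 CPM in WT and 1192 ± 440 in KO (SD, n = 3 each), with each KO library above each WT library. Summed over the whole list they held 1754 ± 54.8 CPM in WT and 2077 ± 352 in KO, with KO 2 at 1756 CPM below WT 3 at 1809. Ccr2 alone gave 927 and 327 CPM of these sums. Lung epithelial markers were less even: of 14 tested, 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.164; 0.0305 without WT 1 and 0.0199 without KO 2). Krt19 rose from 2.38 ± 0.69 to 14.1 ± 4.72 CPM (2.56, adjusted p = 0.002). Scgb1a1, the secretory protein of airway club cells, was at 13.3 ± 9.30 CPM in WT and at 946, 8.47 and 352 CPM in KO 1, KO 2 and KO 3. Its edgeR adjusted p of 0.0285 became 0.101 without KO 1 and between 0.0798 and 0.159 without any one WT library.

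**Figure D2:**
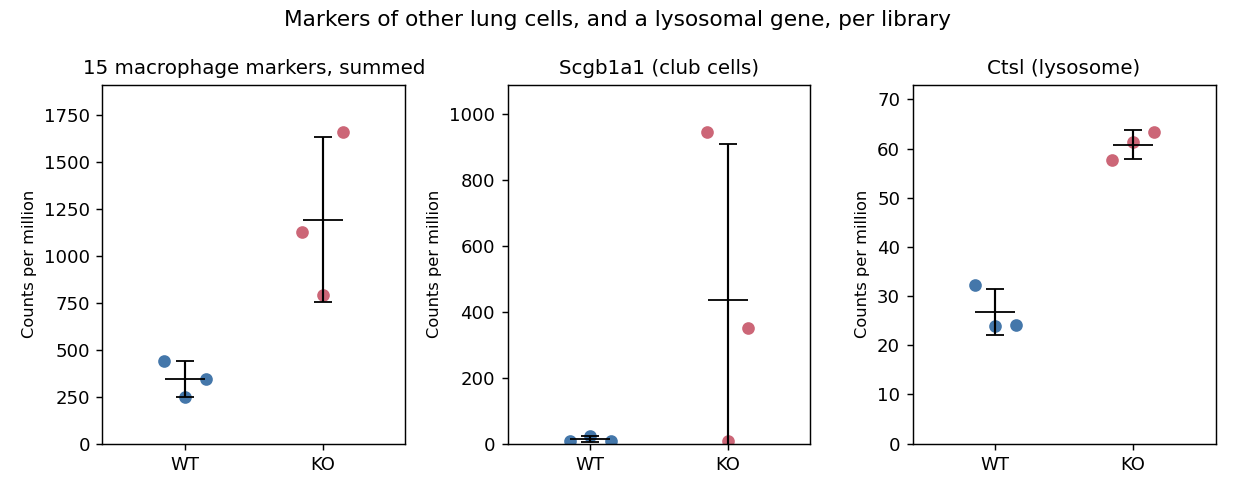
CPM per library of 15 summed macrophage markers, the club cell gene Scgb1a1 and the lysosomal gene Ctsl, on linear vertical axes from 0; points are libraries, horizontal bars means and whiskers the SD, ending at 0 for Scgb1a1 in KO. The summed macrophage markers, picked after the data were examined, average 345 CPM in WT and 1192 in KO. The whole list they came from, not shown, averages 1754 CPM in WT and 2077 in KO, with KO 2 below WT 3. Scgb1a1 is high in KO 1 and KO 3 and at 8.47 CPM in KO 2, and Ctsl is higher in all 3 KO libraries.

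Of the 10 genes with the largest rise, Plet1 belongs to the macrophage list, and Cyp2f2 and Cbr2 are enzymes abundant in club cells. Cyp2f2 was at 38.5, 1.54 and 20.8 CPM in KO 1, KO 2 and KO 3 against 0.54 ± 0.43 in WT, and Cbr2 at 67.8, 8.47 and 28.4 CPM against 2.75 ± 1.36. Npl, an enzyme of sialic acid breakdown, rose from 4.14 ± 0.84 to 39.4 ± 5.67 CPM (3.25, adjusted p = 3.69e-05). Lpl, lipoprotein lipase, rose from 7.86 ± 1.86 to 52.3 ± 13.2 CPM (2.73, adjusted p = 0.000185). The transcription factor gene Creb3l1 (log2 fold change 2.83), the arginine transporter gene Slc7a2 (2.82) and Mgst1 (2.80), a microsomal glutathione transferase, also rose, as did F7 (3.02) and Hp (2.87). Which cells in the libraries the RNA of these 10 genes came from was not tested. Among the 10 largest falls, besides Il17f, Il17a and Ccr6, were Il1rl2, the IL-36 receptor, from 21.045 ± 1.17 to 4.31 ± 2.17 CPM (−2.28, adjusted p = 0.00467), Actn2 (−2.66), Thsd7b (−2.77), Mmp25 (−1.81), Dclk2 (−2.70), Lrrn2 (−2.09) and Gna14 (−1.92). Cyp2f2, Cbr2, F7, Hp, Dclk2, Lrrn2 and Gna14 each lost the threshold without at least 1 of WT 1, WT 2, WT 3 and KO 1 (adjusted p between 0.0519 and 0.173).

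Genes of ribosome production were higher as lists. All but 1 of 79 ribosomal protein genes had a positive fold change (median 0.33, camera adjusted p = 5.43e-21), although 3 passed the threshold singly, among them Rpl12 and Rps3a1 with log2 fold changes of 0.55 and 0.60, and 39 adjusted over the list alone; the adjusted p with an estimated correlation was 0.588. Rpl12 and Rps3a1 lost the threshold in all fits without 1 library but that without KO 3 (0.0654 to 0.206). Rps3a1 is uncertain, since counting could split its reads with its pseudogenes Rps3a2 and Rps3a3, which were singled out after their values were seen. Summed, the 3 genes held 1105 ± 70.3 CPM in WT and 1450.4 ± 233 in KO (SD, n = 3 each), a log2 ratio of 0.39. Of 40 ribosome biogenesis genes 7 rose and none fell, or 15 and none adjusted over the list alone (median 0.25, camera adjusted p = 3.03e-08; 0.304 with an estimated correlation). Grwd1, a ribosome assembly factor, rose from 37.2 ± 1.34 to 80.5 ± 8.55 CPM (1.11, adjusted p = 0.00146) and kept the threshold in all 6 fits that left out 1 library. Nolc1, Mybbp1a and Nop14 rose by 0.67, 0.72 and 0.70 and lost it without any one WT library, the latter pair also without KO 1 (0.0561 to 0.115). Of 27 genes of Myc, its partners and translation factors, Myc and Mxd1 rose, also adjusted over the list alone, by 0.55 and 0.64 (list camera adjusted p = 0.0297; 0.588 with an estimated correlation, 0.131 without WT 1, 0.0913 without KO 2 and 0.111 on the FPKM values). Myc lost the threshold without any one WT library or KO 1, and Mxd1 without WT 1, WT 3 or KO 1 (0.0731 to 0.183). Nuclear-encoded subunits of the respiratory chain passed camera in the lower direction with no member past the edgeR threshold among 74, 16 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (median −0.14, adjusted p = 0.000292; 0.588 with an estimated correlation). Ndufa1 was at 98.5 ± 4.08 CPM in WT and 70.1 ± 7.27 in KO (−0.49, adjusted p = 0.053).

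**Figure D3:**
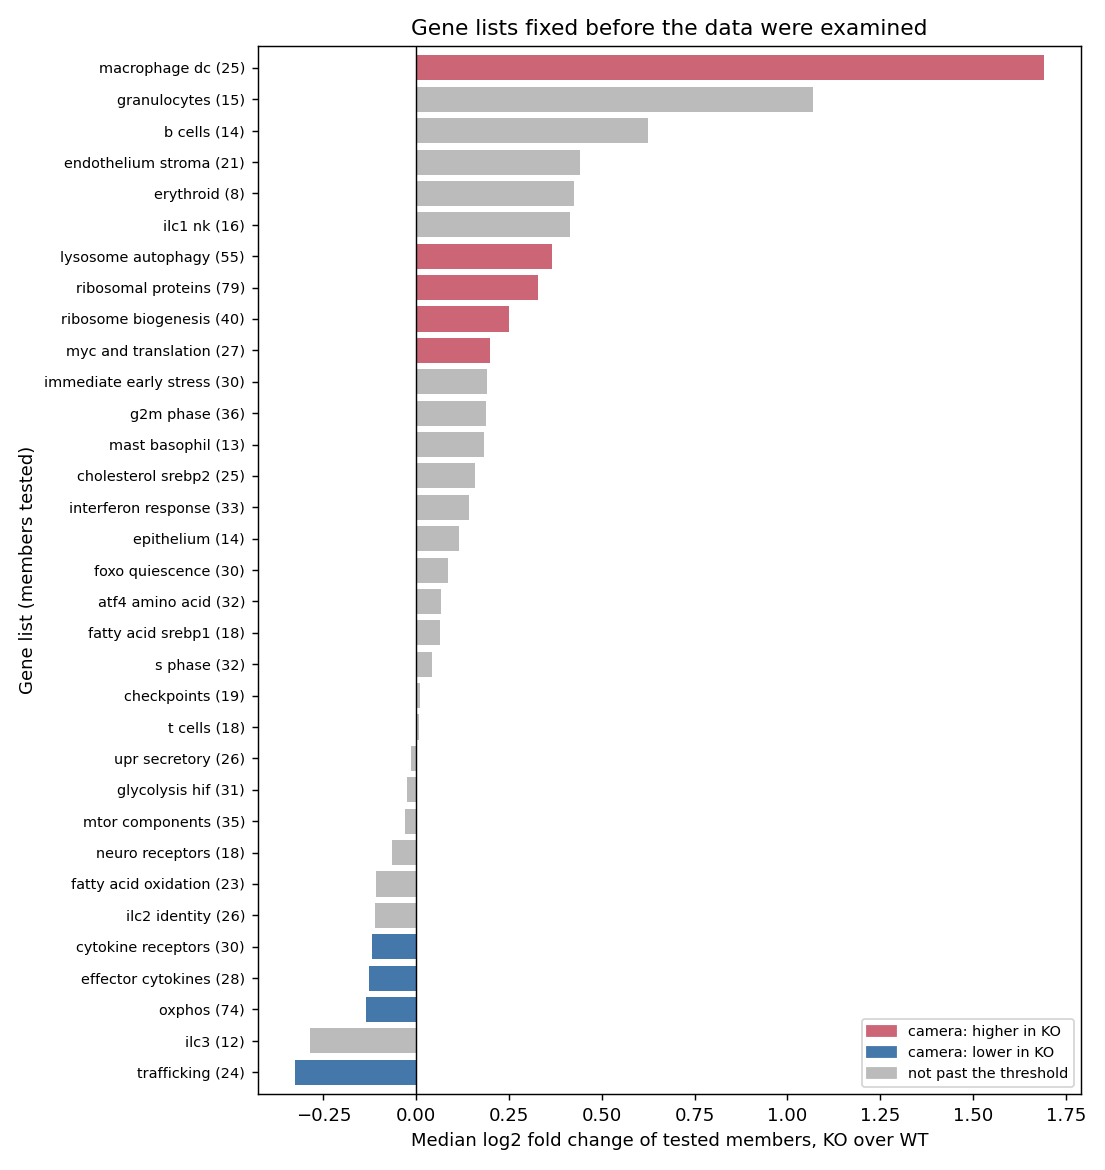
Median log2 fold change of KO over WT for the 33 gene lists, one bar per list with the number of tested members in parentheses. Red and blue bars are the 5 lists higher and the 4 lower in KO by camera at an adjusted p under 0.05, and gray bars are lists that did not pass; with an estimated correlation only the lysosomal list passed (adjusted p = 0.0291).

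The heat shock genes Hsph1, Dnajb1 and Hspa1b rose. Of 30 immediate early and stress genes 5 rose and 2 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.167), among them Hsph1 from 213 ± 9.60 to 573 ± 105 CPM (1.43, adjusted p = 0.000556). Dnajb1 rose from 1140.1 ± 121 to 3075 ± 1068 CPM (1.43, adjusted p = 0.00349). Both kept the threshold in all 6 fits that left out 1 library. Hspa1b rose by 1.30, a call lost without WT 2, WT 3 or KO 1 (0.0519 to 0.0928), and Fos fell by 0.73 on the log2 scale, a call lost without any one WT library (0.0817 to 0.115). These genes also respond to tissue dissociation. Of 30 FOXO targets and quiescence genes 1 rose (Klf2, 0.72) and 2 fell (Klf3, −0.99, and Btg1, −0.83), or 6 and 4 adjusted over the list alone, with a camera adjusted p of 0.415. Klf3 lost the threshold without WT 2 or WT 3, Klf2 without any one WT library, and Btg1 without these or KO 1 (0.0559 to 0.142).

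In the other metabolic and cell cycle lists few members passed. Among 18 fatty acid synthesis genes Acss2, which makes acetyl-CoA from acetate, fell by 0.56 on the log2 scale (adjusted p = 0.045; list 0.47), and among 32 DNA replication genes Mcm2, a helicase subunit, rose by 0.72 (adjusted p = 0.0111; list 0.501). Adjusted over the list alone, 2 rose and 1 fell in the former list and 1 rose in the latter. Acss2 lost the threshold in all fits without 1 library but that without KO 2 (0.0751 to 0.227), and Mcm2 without any one WT library or KO 1 (0.0591 to 0.086). No member passed the edgeR test, over all genes or adjusted over the list alone, among 31 glycolysis and HIF-1 target genes (camera adjusted p = 0.804), 25 cholesterol genes (0.249), 23 fatty acid oxidation genes (0.501), 32 amino acid and ATF4 target genes (0.446), 36 mitotic genes (0.446), 26 genes of the unfolded protein response (0.486) and 33 interferon response genes (0.668). At an unadjusted p under 0.05 they had 4, 7, 2, 5, 3, 4 and 7 members, DESeq2 called 0, 0, 1, 2, 0, 2 and 3, and limma-voom called 0 in each. The glycolysis and fatty acid oxidation lists had a negative median and camera direction but a positive mean. Mki67, a proliferation marker, was at 5.22 ± 0.53 CPM in WT and 4.49 ± 0.80 in KO (−0.22, adjusted p = 0.779).

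Markers of further cell types that a lung sort could hold were also counted. Of 18 T cell markers 2 fell, or 4 adjusted over the list alone. Trbc2 fell from 280.2 ± 38.5 to 173 ± 14.003 CPM (−0.69, edgeR adjusted p = 0.0161). Cd3g fell from 146 ± 25.1 to 79.4 ± 18.4 CPM (−0.87, adjusted p = 0.0216). The list's median was positive, its mean and camera direction negative (adjusted p = 0.305), and both genes lost the threshold without WT 2 or WT 3, Trbc2 also without KO 1 (0.0692 to 0.143). Summed T cell markers were at 993 ± 102 CPM in WT and 700 ± 98.3 in KO (SD, n = 3 each), with each KO library below each WT library. Of 13 mast cell and basophil markers Kit, Hdc and Gata2 rose, the latter pair by 1.12 and 1.33, or 4 rose and 3 fell adjusted over the list alone (list 0.151; 0.038 without WT 3). Hdc lost the threshold without any one WT library or KO 2, and Gata2 without WT 1, WT 2, KO 1 or KO 2 (0.0518 to 0.125). Of 16 ILC1 and NK cell markers Tyrobp, also expressed by macrophages, rose from 20.6 ± 8.42 to 65.8 ± 17.95 CPM (1.68, adjusted p = 0.00877), or 2 rose adjusted over the list alone (list 0.362; 0.0332 without KO 1).

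Of 15 granulocyte markers Cxcl2 fell by 0.85 on the log2 scale, also adjusted over the list alone, while the list's median was positive (list 0.265; 1.3e-06 without KO 1). Of 8 red cell markers Bpgm fell by 0.85, also adjusted over the list alone (list 0.362). Both genes lost the edgeR threshold without any one WT library or KO 1 (adjusted p between 0.0586 and 0.123). Of 14 B cell markers none passed over all genes and 1 was lower adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom (list 0.225; 0.038 without WT 3 and 0.000295 without KO 1). None of 21 endothelial and stromal markers passed, with 7 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom (list 0.164; 0.0249 without WT 3 and 0.0178 without KO 1). Summed B cell markers were uneven, at 206, 833 and 3528 CPM in KO 1, KO 2 and KO 3 and 332 to 1191 in WT. Besides the T cell sum, those of granulocyte markers (1070 ± 55.8 CPM in WT and 719 ± 217 in KO), mast cell and basophil markers (601 ± 70.4 and 1079 ± 44.3) and ILC3 markers (1168 ± 81.2 and 1371 ± 77.8) did not overlap between the groups. Cxcl2 alone held 1001 and 556 CPM of the granulocyte sum, and Kit 377 and 799 CPM of the mast cell and ILC3 sums.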

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

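The alternatives without WT 1 and KO 3 and with the macrophage marker covariate were chosen after the data were seen. The main counts were 302 genes higher and 279 lower. DESeq2 gave 559 and 600, no filter 607 and 495, quality weights 449 and 444, and a log2 fold change above 1 gave 176 and 103. The FPKM values gave 169 and 182 with a pseudocount of 1, 163 and 171 with 0.1 (11212 genes), and 44 and 36 without a filter (23769 genes). Leaving out 1 library gave 88 to 374 higher and 56 to 352 lower. Without WT 1 and KO 3, 117 and 125 were called, of which 188 were also main calls. With the macrophage covariate 5 and 1 were called; the covariate rises with the KO group (variance inflation 7.31), so this fit has little power to separate them. No pairing by replicate number was seen (same-number correlations −0.0507, 0.0591 and −0.0846), and no sample correlated best with its own number. With 3 libraries per group this cannot exclude pairing, on which the labels are silent. The replicate block gave 357 higher and 302 lower. With it the granulocyte list passed (adjusted p = 0.00533), as did Scd2, Cd36, Edem1, Ighm, Ear1 and Tek, while Acss2 (0.0602) and Scgb1a1 (0.112) did not.

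Rptor passed with DESeq2 (−0.5759) and without KO 3, and ranged from −0.7075 to −0.4452 with 1 library left out. Nmur1 missed the threshold with FPKM (−1.041, −1.05 and, unfiltered, −1.041), without WT 1 and KO 3 (−1.029) and with the macrophage covariate (−0.7464), and ranged from −1.357 to −0.837 with 1 library left out. Its direction held in each. Fits without a library have fewer samples; otherwise the cause was not tested.

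The 5 higher and 4 lower lists became 1 and 0 with an estimated correlation, and 1 and 0 with fry. With 1 library left out they ranged from 5 to 9 higher and 2 to 5 lower. Single lists also crossed the threshold, as given above, with the filter of 10 CPM (effector cytokines, cytokine receptors, ILC3) and with FPKM (effector cytokines, Myc and translation, ILC3). Without WT 1 and KO 3, effector cytokines (0.182) and Myc and translation (0.107) no longer passed, while neuropeptide receptors (0.0397) and epithelium (0.0268) did. With the macrophage covariate 5 lists were higher and 1 lower, but not the same lists: ribosome biogenesis (0.238), migration (0.841) and the respiratory chain (0.693) no longer passed, and the interferon list did (0.00762, higher). Under that covariate these results reversed direction: Arg1 0.07599, F7 −0.07232, Plet1 −0.3097, Icos 0.137 and Hspa1b −0.5546, and the lists of effector cytokines (adjusted p 0.225), cytokine receptors (0.159), ILC2 identity (0.0156, now passing as higher), B cells (0.0181, now passing as lower) and macrophages (0.964). No other alternative reversed a result. Of 74 named genes past the threshold, 68 kept it under all count settings with 6 libraries, 32 in all 6 fits without 1 library, and 0 under all settings, the macrophage covariate included. A gene that a filter dropped, as that of 10 CPM dropped Rragd and Lair1, was taken as kept there. The fold change threshold was not applied to single genes in these counts. The count settings ended the calls of Cyp2f2 (adjusted p = 0.316), Cbr2 (0.0866), F7 (0.073), Hp (0.0648) and Scgb1a1 (0.303) with limma-voom, Cyp2f2 and Scgb1a1 also with quality weights (0.125 and 0.0857), and of Acss2 (0.0739) without a filter. Of the genes given above without a call, Gata3 passed with DESeq2, limma-voom with and without quality weights, no filter and the 10 CPM filter (0.0212 to 0.0488). Ndufa1 passed with RLE, upper-quartile scaling, DESeq2, quality weights and the 10 CPM filter (0.0187 to 0.0497), Areg with DESeq2 and quality weights (0.0372 and 0.0477), and Il5 without a filter (0.0238).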

Other observations

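The tests of T cells as a whole, and of the pseudogenes in separate parts, were chosen after the result was seen, as were the limit to members above 10 CPM, the use of WT levels for the pseudogenes and the limit of 5 on variance inflation. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split called 581 genes, the highest of the other splits called 4, and 1 of the 10 splits, the real one, called as many.

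Macrophage markers and lysosomal genes were both higher in KO. For the whole macrophage list the correlation estimated by camera, a different measure, was 0.146. The 15 markers, picked from it after the data were examined, which may raise their correlation, deviated together from library to library within the groups. Their median pairwise correlation of deviations from group means was 0.464, against a 95th percentile of 0.131 over 1000 unpicked random sets of matched expression. This is consistent with macrophage RNA in the sorted cells, in larger amount in KO; the most abundant markers, Lyz2 and Chil3, were at 562 and 378 CPM in KO, and the gates of the sort are not given in the sources used here. Whether that RNA accounts for the whole lysosomal rise cannot be told apart from an effect within ILC2s. With the macrophage score as a covariate the list's median was 0.248 against 0.366 without it. The former lay above 0.183, a bound set before this fit but after the data had been seen. The list passed camera (adjusted p = 0.0181), but the interval over members (0.0472 to 0.405) includes that bound. The score also rises with the KO group (variance inflation 7.31). Loss of mTORC1 signalling in the ILC2s stays open as well: 12 TFEB and TFE3 targets, 11 of them in the lysosomal list, had a median log2 fold change of 0.488 without the covariate, with 4 past the threshold, and of 0.839 with it (interval over genes 0.198 to 1.29), but that fit does not separate group and score.

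Il17a, Il17f and Ccr6 were lower in KO at low levels (Il17f at 16.5 CPM in WT). Fewer IL-17-producing T cells or ILC3, which would lower their other genes too, cannot be told apart from a change within the sorted cells. The median log2 fold change of 14 other genes of such cells was −0.00247 (interval over genes −0.296 to 0.473), but it leans on genes near the floor. Over the 6 at 10 CPM or more in WT the median was −0.392 (−0.698 to −0.121). The T cell list had a median of 0.00703, and its 13 members at 10 CPM or more one of −0.0273 (−0.566 to 0.134), which leaves fewer T cells open as well. Summed over the T cell list, the libraries held 993 ± 102 CPM in WT and 700 ± 98.3 in KO, each KO library below each WT library. Of these sums Trbc2 held 280 and 173 CPM, and Cd3g 146 and 79.4 CPM.

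Rps3a2, a processed pseudogene singled out after its values were seen, was at 139 ± 3.23 CPM in WT and 1.55 ± 0.17 in KO (log2 fold change −6.48, edgeR adjusted p = 1.2e-09), the smallest p of all tested genes; of 9 called processed pseudogenes 5 fell and 4 rose, the latter by log2 fold changes of 0.81 to 1.88. Rps3a2, Rps3a3 and Gm4366 share at least 67.19% of their 31-base words with Rps3a1 or Eef1g, Gm8818 shares 37.07% with another gene, above the tenth set as a bound, and Gm38158 shares 0%, which argues against misassigned reads of a tested coding gene for it; 1 of the 5 that fell, Rps3a3, also has a functional gene at least 10 times as abundant in WT (105 times, against 6.87 for Rps3a2 and 8.35 for Gm4366). Shared words do not decide the fall: Rps3a1 rose by 0.60 (edgeR adjusted p = 0.0363) and Eef1g was at 0.41 (0.119), while a fixed share of misassigned reads would move with the source gene. For the 4 others misassigned reads cannot be told apart from a change of the copies, since a shift in assignment, as from a sequence difference between the mice, was not tested on reads. The counts of processed pseudogenes did not fall in general: the median over 358 of them was 0.258 (interval over genes 0.204 to 0.308). Reads of functional genes assigned to the copies could raise this median. A general fall of the copies' own transcripts was therefore not excluded.

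A strain segment around the floxed Rptor allele stayed open: 7 of 171 genes within 10 Mb passed, 4.09% against 3.99% elsewhere (two-sided Fisher's exact p = 0.844). Gaa, Cbr2 and Socs3, given above, are among the 7. For them an effect of DNA linked to the floxed allele cannot be told apart from the loss of Rptor.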
